A study of Homo sapiens with 6 samples.

How the data were processed

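The series holds 6 samples of RO82-W-1 cells, 2 each of control, ionomycin and BAPTA/AM, which the labels call biological replicates. Total RNA was isolated with RNeasy columns, amplified and labelled with Cy3 or Cy5 by Agilent's method, per the labels' protocols. The protocol also mentions a combination of ionomycin and BAPTA/AM, which is not analysed here. Groups and replicate numbers came from the sample titles and dyes from the label fields.

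The deposited files are outputs of Agilent Feature Extraction 10.5.1.1 with the 2-colour protocol GE2-v5_95_Feb07, per the file headers. The intensity used is the processed signal, which per the file headers was background-subtracted with spatial and multiplicative detrending and then dye-normalised between the channels of an array by linear scaling and LOWESS. It was not scaled between arrays. The design's probe coordinates are on hg18, per the files. All arrays lay on 1 slide. Of the 4 arrays, 1 held control replicate 1 and BAPTA/AM replicate 1, 1 held ionomycin replicate 1 and control replicate 2, and 2 held BAPTA/AM replicate 2 and ionomycin replicate 2, each beside a channel that no label describes. These 2 unlabelled channels, columns of per-sample values with no sample here, entered no comparison of the main fit. The red one, beside ionomycin replicate 2, took the place of that sample in an alternative only. Most files keep the raw columns of the channel their label names. That of ionomycin replicate 2, labelled Cy3, keeps those of the red channel, so its green processed signal was used by the label, with the red channel as an alternative chosen after seeing the data. LOWESS ties the channels of an array to each other. On the arrays shared by control and a treatment it can therefore shrink a change common to many genes.

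The deposited series matrix gives, as a score of unstated scale, centring and direction, values for 5224 probe identifiers per sample. Its column medians were -0.624 and -0.348 for control replicates 1 and 2, -0.331 and 0.230 for BAPTA/AM, and -0.443 and 0.144 for ionomycin. After centring each probe, these values correlated with the scanner values at -0.0318 to 0.0183, so scale, centring and direction stayed unknown and the values were not used.

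For each sample, log2 of the labelled channel's processed intensity was taken minus the log2 of that channel's 75th percentile. Control spots and spots with outlier flags were left out, saturated spots were kept, and spots of one probe were averaged (264 probes had 10 spots). Flags absent from a file were rebuilt. For control replicate 1 they came from the background-subtracted signal, a rule that matched every deposited flag of the other 4 samples it could be checked on. For ionomycin replicate 2 they came from the processed signal, a rule that matched 99.1% to 99.3% of flags elsewhere; its file has no green outlier flags, and its saturation was taken from the net signal. Spots well above background numbered 28511 and 28333 in control replicates 1 and 2, 28612 and 31532 in BAPTA/AM, and 29745 and 26900 in ionomycin, of 43376. Between 40 and 355 of the 26898 tested probes were saturated in a sample. A probe was tested if it was well above background in both samples of at least 1 group. The plan made for arrays holding 2 labelled samples each (loess and quantile steps on both channels) did not apply, since 2 arrays held an unlabelled channel.

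Gene symbols were matched to the RefSeq gene table given: 23958 probes by accession, 2755 by symbol and 1027 by synonym, and 13260 kept the name in the file. Y-linked genes and XIST are left out of the text, and some other genes are not reported here.

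Each comparison was a contrast in limma 3.58.1 (R 4.3.3, lmFit and eBayes, two-sided) over all 6 samples with group and dye as terms, and Benjamini-Hochberg adjustment over 26898 probes at 0.05. Groups shared one estimate of the spread because each has 2 samples; the prior had 1.99 degrees of freedom beside the 2 residual ones. Dye was balanced over groups, except in the alternative with the red channel for ionomycin replicate 2. There both ionomycin samples were Cy5, and the dye effect was estimated from the control and BAPTA/AM groups only. Errors beside log2 fold changes are standard errors, and those beside levels are SDs. Array as a fixed term would leave 0 residual degrees of freedom, so values within shared arrays are given instead, as differences of 1 sample pair with no test.

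Gene lists, 37 in number, were fixed before the data were examined. They cover mitochondria, calcium handling, metabolism, stress responses, proliferation, ribosomes, inflammation, matrix, thyroid function and markers of other cell types. Each gene was represented by its brightest probe on average over the 6 samples. Camera was run with a preset correlation between genes of 0.01, adjusted over 37 lists in 3 comparisons (111 tests), with an estimated correlation and fry as alternatives. With the preset, 41 tests passed, and with an estimated correlation 0 passed, at a lowest adjusted p of 0.42. With the preset, camera's p-values rest on the number of genes and not of samples. Under the estimate, they rest on the 2 residual degrees of freedom, at which hardly any list could pass over 111 tests. The estimates for the hypoxia (-0.0415), glycolysis (-0.0295) and matrix (-0.0156) lists were below the preset, so correlation does not explain their lost calls. That for ribosome biogenesis (0.2301) was above it. So were those for the cytosolic ribosomal (0.2034), G2/M (0.1948), p53 (0.1496), proteasome (0.1218) and ER chaperone (0.1015) lists, among others. For such lists the p-values with the preset may be too low. Counts of list members come from the tests of single probes.

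Named genes followed a rule fixed before the data were examined. Per comparison, it takes the 8 highest and 8 lowest log2 fold changes among named probes past the threshold that were well above background in both samples of the brighter group, not saturated throughout a group, and of one sign in all 4 sample differences, with 1 probe per symbol. Where fewer passed, the lowest p-values filled the 8. It adds up to 4 members of each list past the threshold with the lowest p, and always RCAN1, PPRC1, PPARGC1A, ESRRA, LDHA, LDHB, HSPA5 and MT2A. Other genes named were chosen after their values were seen, as said beside them; S100A4 is one. A probe well above background in no sample of a group has only a bound there. Its fold is the bright group's mean over the dim group's mean of, per array, the higher of its own signal and the lowest signal well above background (-6.76 to -4.77 on the log2 scale).

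The fit was tested on simulated data: 20 simulations of 26898 probes per comparison with 200 changed probes. For BAPTA/AM against control, it called 0.3% of 1.5-fold, 34.2% of 2-fold and 83.7% of 4-fold changes, and 5.03% of calls were false. For ionomycin against control these were 0.3%, 31.0%, 82.7% and 4.67%, and between the treatments 0.15%, 34.1%, 84.3% and 5.02%. A list shifted by 0.3 was found in 20 of 20 simulations in each comparison. The simulated noise was drawn independently for each probe and sample, so these rates do not cover correlated genes or effects of shared arrays. They also hold for 200 changed probes only, since the adjusted p depends on how many probes change. The real data gave 3200 calls for BAPTA/AM against control and 3995 between the treatments, so recovery there may differ.

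Alternatives covered the dye term, replicate number as a block, normexp background correction (offset 50), quantile and median normalization, the filter on dim probes, limma's trend with a robust prior, fits of only the groups compared, a fold of at least 2, the probe chosen per gene and leaving out each sample in turn. The fits leaving out 1 sample had no dye term, which changes both choices at once, and so compare with the fit of all 6 samples with no dye term. They also leave 1 group with a single dye, so comparisons of that group carry the dye effect. A call lost there cannot be put down to the sample alone. Without one sample of a group, the lone sample is assumed to vary like the other groups. The correlation of the treatments' fold changes over different control samples was added after seeing the data, as were the red channel for ionomycin replicate 2, fits of only the groups compared with no dye term, and the shared array as a random block with no dye term (duplicateCorrelation with statmod 1.5.0). Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.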

Results

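Gene expression was measured in RO82-W-1, an established line from a human follicular thyroid carcinoma, after calcium inside the cells was raised or bound. Ionomycin is an ionophore that carries calcium across membranes, and it was given at 2 µM in medium with 2 mM calcium. BAPTA/AM is a cell-permeant chelator that binds calcium in the cytosol. The labels give its dose as 6 µM in the series title and as 2, 4, 6 and 8 µM on successive days in the treatment protocol. They give the exposure as 5 h a day for 4 days in one place and as 96 h in another, and the control cells as given the solvent in one place and as untreated in another. There were 6 samples, 2 in each of the control, ionomycin and BAPTA/AM groups. The labels call them biological replicates without saying what was kept separate. Limma's p-values for single probes therefore measure only the spread between these samples, which may be technical. Camera's p-values with the preset correlation set the members of a list against the other genes. They rest on the number of genes rather than of samples, and so do not measure that spread.

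Each sample was one dye channel of an Agilent whole-genome array, and 1 sample of each group carried Cy3 and the other Cy5. Between 62.0% (ionomycin replicate 2) and 72.7% (BAPTA/AM replicate 2) of 43376 spots lay well above background. The 75th percentile of the processed intensity ran from 1315 in control replicate 2 to 2548 in BAPTA/AM replicate 2. Of 41000 probes, 26898 passed the filter on dim probes and were tested, and they named 13157 genes. The number of arrays limits the precision: the fit had 2 residual degrees of freedom, and the median standard error of a log2 fold change was 0.083. The first principal component took 47.2% of the variance and put the BAPTA/AM samples at 35.44 and 42.33, apart from the other 4 samples at -34.44 to -4.72. The second took 23.6% and set ionomycin replicate 2 apart, at 35.82. Across probes, the samples of a group differed with an SD of 0.31 on the log2 scale for control, 0.30 for BAPTA/AM and 0.39 for ionomycin.

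**Figure D1:**
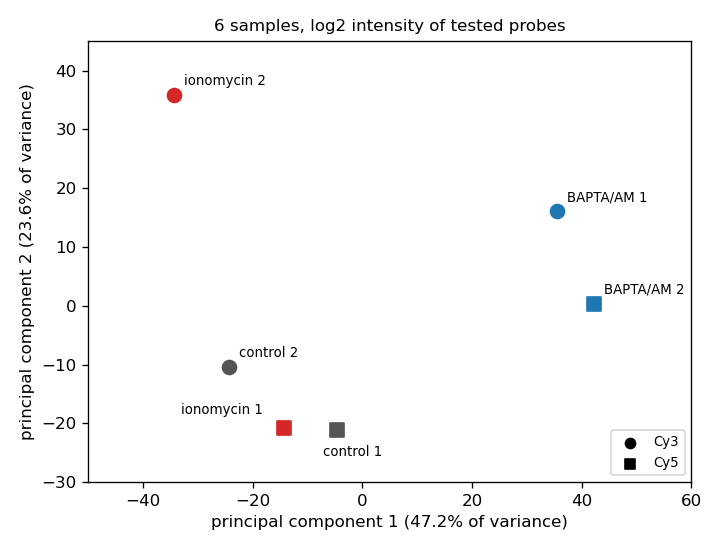
Principal components 1 and 2 of the log2 intensities of the tested probes, with the percent of variance on each axis. Each symbol is 1 of the 6 samples, coloured by group, with circles for Cy3 and squares for Cy5; the BAPTA/AM samples lie at 35.44 and 42.33 on the first component and ionomycin replicate 2 at 35.82 on the second.

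The first comparison asked which genes differed when calcium was chelated, BAPTA/AM against control. As lists tested by camera with its preset correlation, hypoxia-responsive, glycolytic and extracellular matrix genes were lower in the chelated cells (16 of 23, 11 of 25 and 25 of 54 members fell). Ribosome assembly and cytosolic heat shock genes were higher as lists (14 of 45 and 5 of 24 rose). With an estimated correlation the calls were lost, at an adjusted p of 0.42 for the first 3 lists, 0.564 for ribosome assembly and 0.544 for heat shock. That form of the test has only 2 degrees of freedom, so a lost call by itself says little about correlation between genes. The estimates for ribosome assembly (0.2301) and heat shock (0.0523) were above the preset of 0.01, so their preset p-values may be too low. DDIT4, a stress-induced inhibitor of mTOR signalling, was 2.34-fold lower (log2 intensity relative to the 75th percentile 3.07 ± 0.13 against 4.30 ± 0.01, SD, n = 2). LUM, which encodes the matrix proteoglycan lumican, was 3.05-fold lower (-1.06 ± 0.08 against 0.55 ± 0.05, SD, n = 2). HSPH1, a chaperone of the HSP110 family, was 1.93-fold higher (4.42 ± 0.03 against 3.47 ± 0.03, SD, n = 2). RRS1, a ribosome assembly factor, was 1.67-fold higher (3.15 ± 0.23 against 2.41 ± 0.13, SD, n = 2).

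In limma's fit of all 6 samples, 3200 probes passed an adjusted p of 0.05 in this comparison, 1575 higher and 1625 lower with BAPTA/AM. They named 2043 genes, 951 higher and 1103 lower, of which 11 had probes in both directions. Of the 3200 probes, 402 changed at least 2-fold, 188 higher and 214 lower. With normexp background correction the split was 1104 higher and 1986 lower. The lowest adjusted p in the comparison was 0.0185. Control replicate 1 and BAPTA/AM replicate 1 shared an array. Over all 26898 probes, the difference between them and that between the other samples of these groups had the same sign in 67.4% (r = 0.423 across probes, with opposite dye orientation), and with the control samples exchanged, so that each difference lay within 1 dye, in 74.3% (r = 0.593). In every comparison and list test, the fits that left out 1 sample also had no dye term. They are therefore set beside the fit of all 6 samples with no dye term, which called 2511 probes here. Leaving out 1 sample also left its group with a single dye, so a call lost in such a fit may come from the dye. Without control replicate 1, control replicate 2 or BAPTA/AM replicate 2 the count was 0, without BAPTA/AM replicate 1 it was 1, and without either ionomycin sample it was 1176. The fits with 0 calls had 5703, 4532 and 5904 probes at an unadjusted p under 0.05. The count was also 0 by limma with dim probes kept (7368 at an unadjusted p under 0.05), with only these groups and the dye term in the fit (8319), or with the red channel taken for ionomycin replicate 2 (3383).

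Hypoxia targets were the list with the lowest adjusted p in this comparison, with the matrix list at the same value. Of 23 measured members, 16 fell and 1 rose, with 17 lower and 1 higher adjusted over the list alone, and the median log2 fold change was -0.68. Limma's camera test gave an adjusted p of 3.02e-08 with its preset correlation between genes, and adjusted p = 0.42 with an estimated correlation. The members that fell included MXI1, a MYC antagonist, at -1.26 ± 0.08 (SE), DDIT4 at -1.23 ± 0.07 and BNIP3, a mitochondrial mitophagy receptor, at -1.18 ± 0.08, each with an adjusted p of 0.0185. ANGPTL4, a secreted inhibitor of lipoprotein lipase, was the member that rose, by 1.49 ± 0.07. The list median was -0.64 on the array shared by control replicate 1 and BAPTA/AM replicate 1, and -0.61 between the other samples of the groups. The DDIT4 probe lies at chromosome 10, 73705369 to 73705428 (hg18, per the files).

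Glycolysis and lactate genes, of which PDK1, SLC2A1 and SLC2A3 are also on the hypoxia list, shared that direction. Of 25 measured members, 11 fell and 0 rose (12 lower adjusted over the list alone), the median was -0.32, and camera gave an adjusted p of 8.86e-06 (adjusted p = 0.42 with an estimated correlation). PFKFB4, which sets the level of the glycolytic activator fructose bisphosphate, changed by -1.24 ± 0.08, the enolase ENO2 by -0.97 ± 0.06, the hexokinase HK2 by -0.91 ± 0.07 and the glucose transporter SLC2A3 by -0.74 ± 0.06. The median was -0.16 within the shared array and -0.74 between the other samples. Of the lactate dehydrogenase subunits, LDHB (-0.05 ± 0.13, adjusted p = 0.809) and the brightest LDHA probe (-0.44 ± 0.18, adjusted p = 0.178) did not pass, and the levels of both probes followed the dye: within the shared array the differences were 0.66 for LDHA and 0.85 for LDHB. Each of these 2 probes was saturated in 1 of the 4 samples compared, so the differences are not exact. Of the 2 other LDHA probes, 1 passed in the lower direction, at -0.98 ± 0.07 (adjusted p = 0.0185).

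Extracellular matrix and mesenchymal genes were lower as a list. Of 54 measured members, 25 fell and 3 rose (28 lower and 5 higher adjusted over the list alone), with a median of -0.46 and an adjusted p of 3.02e-08 by camera (adjusted p = 0.42 with an estimated correlation). COL3A1, a fibrillar collagen, changed by -1.78 ± 0.07, LUM by -1.61 ± 0.06, COL8A1 by -1.48 ± 0.07 and COL5A2 by -1.10 ± 0.06. The fibroblast marker list shares COL1A1, COL1A2, COL3A1, DCN and LUM with the matrix list, so the lists are not separate evidence. Of its 11 measured members, 6 fell and 1 rose (8 lower and 1 higher adjusted over the list alone). COL3A1, LUM, COL1A1 and DCN, among those that fell, lie on both lists. The fibroblast list had a median of -0.73 and an adjusted p of 9.08e-05 (adjusted p = 0.42 with an estimated correlation). The growth factor receptors PDGFRB and PDGFRA changed by -1.77 ± 0.06 and -1.29 ± 0.07, and S100A4, a calcium-binding protein chosen after its value was seen, rose by 0.98 ± 0.06. Within the shared array the medians were -0.28 for the matrix list and -0.72 for the fibroblast list, and between the other samples -0.75 and -1.03.

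Ribosome biogenesis genes and MYC targets were higher. Of 45 measured members, 14 rose and 0 fell (26 higher and 1 lower adjusted over the list alone), the median was 0.32, and camera gave an adjusted p of 3.09e-08 (adjusted p = 0.564 with an estimated correlation). RRS1 changed by 0.74 ± 0.08, NOP16 by 0.59 ± 0.06, the pseudouridine synthase DKC1 by 0.51 ± 0.06 and the nucleolar chaperone NOLC1 by 0.50 ± 0.06. The list median was 0.37 within the shared array and 0.34 between the other samples. The mitochondrial ribosome list had a median of 0.11 over 68 members, with 3 higher and 0 lower (0 adjusted over the list alone), and an adjusted p of 0.00107 (adjusted p = 0.55 with an estimated correlation). Cytosolic heat shock genes had a median of 0.26, with 5 of 24 higher and 0 lower (11 higher and 1 lower adjusted over the list alone), and an adjusted p of 7.09e-04 (adjusted p = 0.544 with an estimated correlation). HSPA6, a strictly inducible HSP70, changed by 1.12 ± 0.08, HSPH1 by 0.95 ± 0.07 and CHORDC1, an HSP90 co-chaperone, by 0.84 ± 0.07, and the list median was 0.36 within the shared array and 0.205 between the other samples.

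The ATF4, ER chaperone and p53 target lists leaned downwards, while the NRF2, antioxidant and metallothionein lists did not pass camera. The ATF4 and amino acid stress list had 9 of 40 members lower and 2 higher (13 lower and 2 higher adjusted over the list alone), with a median of -0.20 and an adjusted p of 4.64e-04 (adjusted p = 0.42 with an estimated correlation). VLDLR, a lipoprotein receptor, changed by -0.96 ± 0.09, the growth factor VEGFA by -0.70 ± 0.07 and PCK2, a mitochondrial enzyme of gluconeogenesis, by -0.47 ± 0.06. VEGFA and DDIT4 of this list are also on the hypoxia list. ER chaperone genes had 6 of 33 lower and 1 higher (9 lower and 1 higher adjusted over the list alone), a median of -0.17 and an adjusted p of 0.0387 (adjusted p = 0.631 with an estimated correlation). Among them, CALR, which encodes the calcium-binding chaperone calreticulin, changed by -0.57 ± 0.08, PDIA6 by -0.51 ± 0.06 and HSPA5, the ER chaperone BiP, by -0.52 ± 0.09. The p53 target list had 3 of 29 lower and 0 higher (7 lower and 2 higher adjusted over the list alone), with SESN1 at -0.88 ± 0.10, a median of -0.15 and an adjusted p of 0.0411 (adjusted p = 0.677 with an estimated correlation). The ER and p53 calls were lost with no dye term (adjusted p = 0.0566 for each with all 6 samples). In the fits that also left out 1 sample, the ER list had an adjusted p of 0.211 without BAPTA/AM replicate 2, 0.141 without control replicate 2, 0.0585 without ionomycin replicate 1 and 0.0501 without ionomycin replicate 2. The p53 list had 0.154 without BAPTA/AM replicate 1, 0.178 without control replicate 2 and 0.057 without ionomycin replicate 1. Within the shared array the medians were -0.13 for the ATF4 list, -0.03 for the ER list and -0.13 for the p53 list, and between the other samples -0.26, -0.245 and -0.23.

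Lists of calcium handling, the cell cycle and inflammation also passed camera. In the list of calcium pumps, channels and stores, 2 of 31 measured members fell and 1 rose (the same numbers adjusted over the list alone), with a median of -0.18 and an adjusted p of 0.0387 (adjusted p = 0.544 with an estimated correlation). The phospholipase gene PLCB1 changed by -0.68 ± 0.08 and the calcium release channel gene RYR2 by 0.92 ± 0.11. The G2/M list had 1 of 67 members higher and 0 lower (0 adjusted over the list alone), a median of 0.08 and an adjusted p of 0.00769 (adjusted p = 0.714 with an estimated correlation). The G1/S list had 5 of 63 higher and 2 lower (8 higher and 2 lower adjusted over the list alone), a median of 0.08 and an adjusted p of 0.0441 (adjusted p = 0.544 with an estimated correlation); GINS1, of the replicative helicase, changed by 0.57 ± 0.06. NF-kB and inflammatory genes had 4 of 25 higher and 1 lower (7 higher and 2 lower adjusted over the list alone), with CSF2 at 0.84 ± 0.06, IL1A at 0.76 ± 0.08, a list median of 0.14 and an adjusted p of 0.0387 (adjusted p = 0.544 with an estimated correlation). With no dye term these 4 calls held over all 6 samples. The calcium list was lost without control replicate 1 (adjusted p = 0.0612) or BAPTA/AM replicate 2 (0.0647), the G2/M list without BAPTA/AM replicate 1 (0.154) or control replicate 2 (0.0653), the G1/S list without control replicate 1 (0.0781) or BAPTA/AM replicate 1 (0.0764), and the NF-kB list without control replicate 2 (0.105) or BAPTA/AM replicate 2 (0.0742). Within the shared array the medians were -0.23, 0.14, 0.12 and 0.09 for the calcium, G2/M, G1/S and NF-kB lists, and between the other samples -0.18, 0.09, 0.04 and 0.18.

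Among the largest single changes were those of VCX2, VCX and VCX3A, near-identical members of a testis-expressed family on chromosome X, which rose by 3.29 ± 0.07, 3.21 ± 0.14 and 3.0 ± 0.12, each with an adjusted p of 0.0185. Their probes may not tell the copies apart, and those for VCX2 and VCX were well above background in 1 of the 2 control samples. DEFB103B, a beta-defensin gene with a near-identical copy, rose by 2.76 ± 0.44 (adjusted p = 0.0401). ACTC1, which encodes cardiac alpha-actin, changed by -2.75 ± 0.08 by a probe well above background in all control and BAPTA/AM samples, while its other probe stood at -0.39 ± 0.08 (adjusted p = 0.0534). Where a gene was not well above background in either sample of a group, its fold is a lower bound set by the dimmest probes well above background on those arrays. By that bound MED18, a Mediator subunit, was at least 17.6-fold lower, PCDH19 at least 3.28-fold, POSTN, which encodes the matrix protein periostin, at least 2.92-fold, GABRB1 at least 2.91-fold, SPRY1, a feedback inhibitor of growth factor signalling, at least 2.77-fold and VIT at least 1.98-fold lower. In the other direction GRAMD1C was at least 4.69-fold higher, although another of its probes passed in the opposite direction, PTPN22 at least 2.40-fold and GREB1 at least 1.68-fold higher.

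The second comparison asked which genes differed when calcium was raised, ionomycin against control. No single gene passed the test. As lists tested by camera with its preset correlation, the NF-kB, interferon and cholesterol synthesis genes were higher and the ER chaperones lower. With an estimated correlation these calls were lost (adjusted p = 0.42 for the first 3 and 0.564 for the ER list), and the NF-kB and ER calls also with the red channel for ionomycin replicate 2 (adjusted p = 0.24 and 0.174). BIRC3, an inhibitor of apoptosis induced through NF-kB, was 2.09-fold higher with ionomycin (2.48 ± 0.04 against 1.41 ± 0.02, SD, n = 2), with an adjusted p of 0.38 by limma. HSPA5 was 1.84-fold lower (1.73 ± 0.00 against 2.61 ± 0.02, SD, n = 2), with an adjusted p of 0.425. Limma called 0 of 26898 probes at an adjusted p of 0.05, and the lowest adjusted p was 0.38. At an unadjusted p under 0.05 there were 2714 probes (10.1%), where chance gives 5%. With the red channel for ionomycin replicate 2 there were only 418 of 26898, below that share. In that alternative both ionomycin samples were Cy5, so the channel and the dye balance changed together. Over all probes, 2 estimates of the change with no sample in common had the same sign in 50.9% (r = -0.161 across probes) when of opposite dye orientation and in 61.2% (r = 0.074) when each lay within 1 dye. Limma with a mean-variance trend and a robust prior called 14 probes, 7 higher and 7 lower. In limma's fits with no dye term the count was 0 with all 6 samples (1951 at an unadjusted p under 0.05), 30 without ionomycin replicate 1 and 1 without either BAPTA/AM sample.

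NF-kB and inflammatory genes had a median of 0.23 over 25 measured members, of which 21 were positive, and an adjusted p of 2.24e-09 by camera (adjusted p = 0.42 with an estimated correlation). Over all probes 0 members passed, and 10 were higher adjusted over the list alone. BIRC3 stood at 1.06 ± 0.06, the chemokines CXCL1 and CXCL2 at 0.66 ± 0.07 and 0.42 ± 0.06, and the growth factor CSF2 at 0.45 ± 0.06, each with the same sign in all 4 differences between a treated and a control sample. ER chaperone genes had a median of -0.11 over 33 members and an adjusted p of 3.13e-04 (adjusted p = 0.564 with an estimated correlation), with 0 members past the test and 2 lower adjusted over the list alone. HSPA5 stood at -0.88 ± 0.09, and at -0.97 ± 0.08 by its other probe, CALR at -0.56 ± 0.08 and SDF2L1 at -0.41 ± 0.08. Ionomycin replicate 1 and control replicate 2 shared an array, and within it the medians were 0.24 for the NF-kB list and -0.13 for the ER list, against 0.23 and -0.07 between the other samples. The label of ionomycin replicate 2 says Cy3 but its file keeps the raw columns of the red channel. Without that sample and with no dye term both calls held, with medians of 0.24 (adjusted p = 8.21e-11) and -0.12 (adjusted p = 4.48e-04), but with its red channel they were lost. With the red channel the NF-kB median was 0.04 (adjusted p = 0.24), and CXCL1 (-0.43), CSF2 (-0.32) and CXCL2 (-0.13) turned negative. The ER median was then -0.05 (adjusted p = 0.174). The BIRC3 probe lies at chromosome 11, 101713566 to 101713625 (hg18, per the files).

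Interferon-response genes had a median of 0.16 over 42 measured members, with 35 positive and an adjusted p of 3.02e-08 (adjusted p = 0.42 with an estimated correlation), and 0 passed either over all probes or adjusted over the list alone. MX1 stood at 0.62 ± 0.12, XAF1 at 0.55 ± 0.10, OAS3 at 0.39 ± 0.07 and SAMD9 at 0.34 ± 0.06, and with the red channel for ionomycin replicate 2 SAMD9 was -0.04. Cholesterol synthesis genes had a median of 0.17 over 25 members, with 21 positive, 0 past the test and 1 higher adjusted over the list alone, and an adjusted p of 3.52e-06 (adjusted p = 0.42 with an estimated correlation). HMGCS1, an early enzyme of the pathway, stood at 0.50 ± 0.06. Within the shared array the medians were 0.13 for the interferon list and 0.12 for the cholesterol list, against 0.19 and 0.20 between the other samples.

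The other lists past the threshold with ionomycin moved by about 0.1 or less, and 0 of their members passed either over all probes or adjusted over the list alone. Replication-dependent histones had a median of 0.10 (adjusted p = 7.36e-04, and adjusted p = 0.55 with an estimated correlation), epithelial adhesion genes 0.09 (0.0485, and 0.564 with an estimated correlation) and G1/S genes 0.05 (0.0037, and 0.452 with an estimated correlation). The proteasome list had a median of -0.09 (adjusted p = 7.37e-04, and adjusted p = 0.564 with an estimated correlation), ribosome biogenesis -0.085 (0.0252, and 0.73 with an estimated correlation), the TCA cycle -0.065 (0.0222, and 0.555 with an estimated correlation) and the mitochondrial ribosome -0.04 (0.0387, and 0.597 with an estimated correlation). Members with the lowest p included the replicative helicase gene MCM4 at -0.43 ± 0.07, the histone H4C2 at 0.31 ± 0.10, the claudin CLDN1 at 0.41 ± 0.08, the proteasome ATPase PSMC2 at -0.29 ± 0.08 and the citrate synthase gene CS at -0.30 ± 0.09. With no dye term, the calls for the lists named here, apart from epithelial adhesion, held over all 6 samples. Without ionomycin replicate 1 those for histones (adjusted p = 0.196), the proteasome (0.179), ribosome biogenesis (0.204), the TCA cycle (0.302) and the mitochondrial ribosome (0.204) were lost. Without control replicate 1 those for ribosome biogenesis (0.0916) and G1/S (0.0787) were lost, without control replicate 2 those for the TCA cycle (0.16) and the mitochondrial ribosome (0.25), and without ionomycin replicate 2 that for G1/S (0.259). The epithelial call was lost with no dye term (adjusted p = 0.113 with all 6 samples, and 0.0754 to 0.292 without any 1 of them), and the G1/S median was -0.16 with the red channel for ionomycin replicate 2.

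The genes with the lowest p in this comparison, none of them past the threshold, were led in the higher direction by BIRC3, the bone matrix protein gene SPP1 (0.79 ± 0.06), RAB39B (0.85 ± 0.08), the collagenase gene MMP1 (0.83 ± 0.08), SLITRK6 (0.91 ± 0.09), GPNMB (0.63 ± 0.06) and the long noncoding RNA UCA1 (0.62 ± 0.06). EREG, a ligand of the EGF receptor, was at least 1.99-fold higher, being not well above background in either control sample. In the lower direction were STRIP2 (-1.46 ± 0.08), RAB2B (-1.27 ± 0.07), TEP1 (-1.50 ± 0.11), ZNF429 (-1.17 ± 0.10), the cholesterol exporter gene ABCA1 (-1.0 ± 0.09) and TMEM19 (-0.73 ± 0.06), of which TEP1 and ABCA1 were well above background in 1 of the 2 ionomycin samples. MED18 was at least 9.78-fold lower. With the red channel for ionomycin replicate 2, EREG was -0.19 and UCA1 -0.15.

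**Figure D2:**
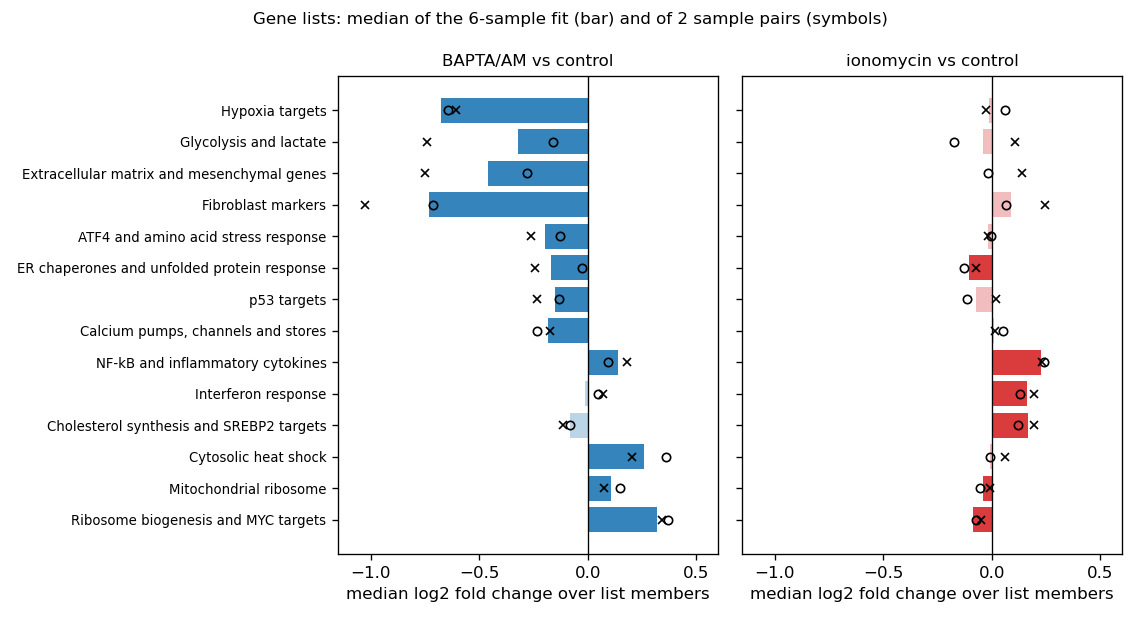
Median log2 fold change over the members of 14 gene lists, with BAPTA/AM against control on the left and ionomycin against control on the right. Bars give the fit of all 6 samples, dark where camera's adjusted p was under 0.05, circles the pair of samples on a shared array and crosses the pair of the other samples of the groups; the hypoxia list stands at -0.64 and -0.61 in the pairs with BAPTA/AM, and the NF-kB list at 0.24 and 0.23 in those with ionomycin.

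Genes linked to mitochondrial biogenesis and to calcineurin were followed in every comparison. PPRC1, a coactivator related to PGC-1 alpha, rose with BAPTA/AM by 0.39 ± 0.06 (adjusted p = 0.0397 by limma) and stood at -0.01 ± 0.06 with ionomycin (adjusted p = 0.981). PPARGC1A, which encodes PGC-1 alpha, stood at -0.27 ± 0.07 with BAPTA/AM (adjusted p = 0.078) and at 0.39 ± 0.07 with ionomycin (adjusted p = 0.425), and its difference between the treatments passed the test at 0.66 ± 0.07 (adjusted p = 0.0233). ESRRA, a nuclear receptor partner of both, stood at 0.28 ± 0.08 with BAPTA/AM (adjusted p = 0.102) and 0.08 ± 0.08 with ionomycin (adjusted p = 0.73). RCAN1, a calcineurin inhibitor that is itself a calcineurin target, stood at -0.28 ± 0.06 with BAPTA/AM (adjusted p = 0.0659) and -0.09 ± 0.06 with ionomycin (adjusted p = 0.635), and at 0.06 with the red channel for ionomycin replicate 2. The probe of the metallothionein gene MT2A was saturated in both BAPTA/AM samples, 1 control sample and 1 ionomycin sample. Any size of change for MT2A is therefore not exact, and none is given here. The probes of PPRC1 and PPARGC1A lie at chromosome 10, 103899679 to 103899738, and chromosome 4, 23403035 to 23403094 (hg18, per the files).

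**Figure D3:**
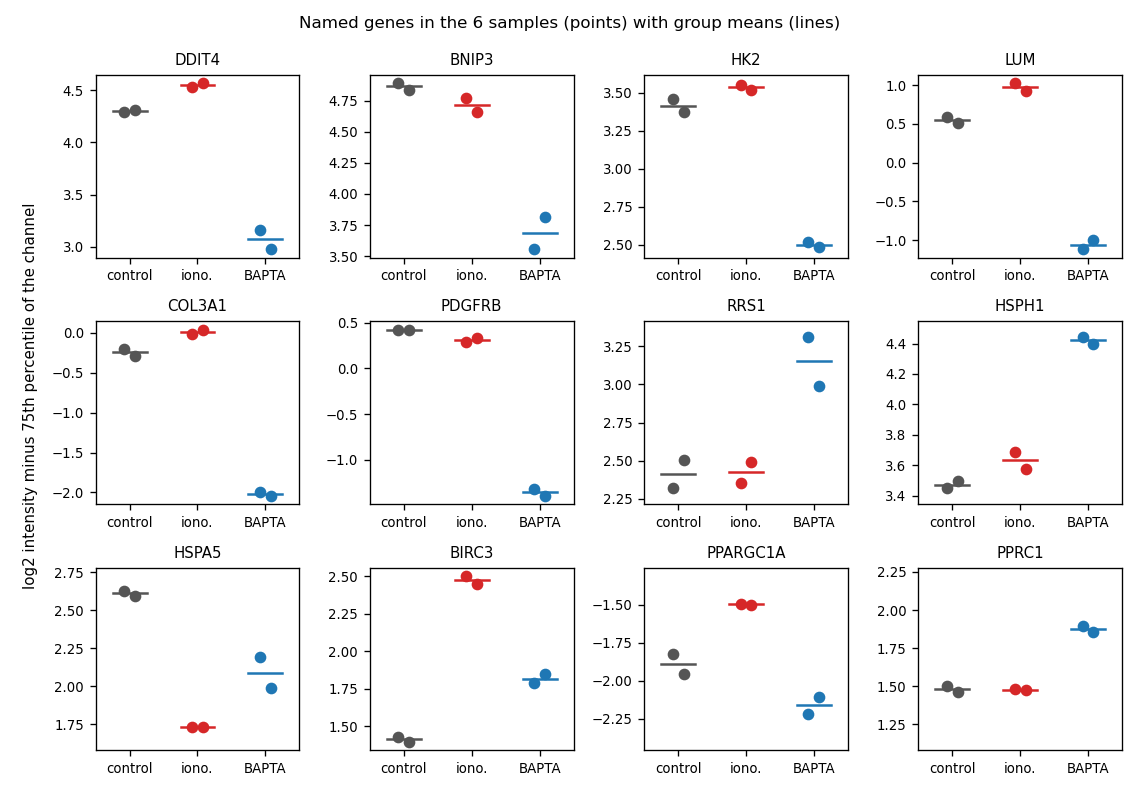
Log2 intensity relative to the 75th percentile of the channel for 12 named genes in the 6 samples. Points are samples, lines group means and colours the groups, and each panel has its own axis; DDIT4 lies at 4.30 in control and 3.07 in BAPTA/AM on average, BIRC3 at 1.41 in control and 2.48 in ionomycin.

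The third comparison set the treatments against each other. As lists tested by camera with its preset correlation, matrix, hypoxia, glycolytic and cholesterol synthesis genes were higher with ionomycin than with BAPTA/AM (28 of 54, 16 of 23, 10 of 25 and 6 of 25 members). Ribosome assembly and heat shock genes were lower as lists (22 of 45 and 4 of 24, with 1 heat shock gene higher). With an estimated correlation the calls were lost, at an adjusted p of 0.42 for the first 3 lists, 0.452 for cholesterol synthesis, 0.564 for ribosome assembly and 0.544 for heat shock. DIO2, the deiodinase that activates thyroid hormone, was 5.87-fold higher with ionomycin than with BAPTA/AM (-0.93 ± 0.18 against -3.48 ± 0.16, SD, n = 2). ACTC1 was 7.08-fold higher (2.82 ± 0.02 against 0.00 ± 0.11, SD, n = 2) by the probe that fell more in the BAPTA/AM comparison. Its other probe did not pass in that comparison. Limma called 3995 probes, 1974 higher and 2021 lower with ionomycin, of 2595 genes, and 441 of the probes differed at least 2-fold, 253 higher and 188 lower. With normexp background correction the split was 2398 higher and 1482 lower. Of the 3200 probes called for BAPTA/AM against control, 2468 were called here as well, 2464 of them on the side that the BAPTA/AM change gives, and 1527 probes called here were not called there. Of the 2464, 1185 were higher with BAPTA/AM than in both other groups and 1279 lower, where independent lists would share 118.3 and 119.3; both comparisons use the same BAPTA/AM samples, which adds to the overlap by itself. No array held samples of both treatments, so no value within an array could be had. With no dye term the count was 3039 with all 6 samples, 0 without BAPTA/AM replicate 1, BAPTA/AM replicate 2 or ionomycin replicate 2, 387 without either control sample and 1265 without ionomycin replicate 1. The fits with 0 calls had 6865, 6837 and 5882 probes at an unadjusted p under 0.05. The count was also 0 by limma with dim probes kept (8305 at an unadjusted p under 0.05), with only these groups and the dye term in the fit (8223), or with the red channel for ionomycin replicate 2 (4455).

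Extracellular matrix genes had a median difference of 0.49, with 28 of 54 higher and 3 lower (30 and 5 adjusted over the list alone), and an adjusted p of 3.02e-08 (adjusted p = 0.42 with an estimated correlation). Fibroblast markers had 0.86, with 8 of 11 higher and 1 lower (the same adjusted over the list alone) and an adjusted p of 5.87e-05 (adjusted p = 0.42 with an estimated correlation). LUM differed by 2.04 ± 0.06 and COL3A1 by 2.03 ± 0.07. Hypoxia targets had 0.63, with 16 of 23 higher and 1 lower (18 and 1 adjusted over the list alone) and an adjusted p of 1.14e-07 (adjusted p = 0.42 with an estimated correlation), and DDIT4 differed by 1.48 ± 0.07. Glycolysis genes had 0.25, with 10 of 25 higher and 0 lower (13 and 1 adjusted over the list alone) and an adjusted p of 4.83e-04 (adjusted p = 0.42 with an estimated correlation). Cholesterol synthesis genes had 0.25, with 6 of 25 higher and 0 lower (12 and 0 adjusted over the list alone) and an adjusted p of 1.64e-04 (adjusted p = 0.452 with an estimated correlation), led by SREBF2, the pathway's transcription factor, at 0.73 ± 0.07 and HMGCS1 at 0.58 ± 0.06. The ATF4 list had 0.20, with 9 of 40 higher and 2 lower (15 and 3 adjusted over the list alone) and an adjusted p of 0.00107 (adjusted p = 0.42 with an estimated correlation). Calcium pumps, channels and stores had 0.15, with 5 of 31 higher and 0 lower, also adjusted over the list alone, and an adjusted p of 0.0212 (adjusted p = 0.544 with an estimated correlation). TRPC1 and ITPR2, calcium channels of the cell surface and the ER, differed by 0.55 ± 0.08 and 0.89 ± 0.15. Fatty acid synthesis genes had 0.14, with 4 of 18 higher and 0 lower, also adjusted over the list alone, and an adjusted p of 0.0296 (adjusted p = 0.564 with an estimated correlation), and the desaturase genes SCD and FADS2 differed by 1.02 ± 0.10 and 0.78 ± 0.08. With no dye term both of these calls held over all 6 samples, and without BAPTA/AM replicate 2 the calcium list (adjusted p = 0.0524) and the fatty acid list (0.113) were lost.

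Ribosome biogenesis genes were lower with ionomycin than with BAPTA/AM by a median of -0.35, with 22 of 45 lower and 0 higher (31 and 0 adjusted over the list alone), and an adjusted p of 2.24e-09 (adjusted p = 0.564 with an estimated correlation). The mitochondrial ribosome list had -0.16, with 8 of 68 lower and 0 higher (0 adjusted over the list alone) and an adjusted p of 3.43e-05 (adjusted p = 0.544 with an estimated correlation). Heat shock genes had -0.32, with 4 of 24 lower and 1 higher (13 and 1 adjusted over the list alone) and an adjusted p of 9.45e-04 (adjusted p = 0.544 with an estimated correlation); HSPA6, well above background in 1 of the 2 ionomycin samples, differed by -1.31 ± 0.08, and CRYAB, a small heat shock protein, by 1.48 ± 0.11 in the other direction. The proteasome (-0.11, 1 of 31 lower, 0 adjusted over the list alone) and G2/M (-0.10, 3 of 67 lower, 0 adjusted over the list alone) lists had adjusted p of 0.0132 and 0.0184 (adjusted p = 0.6 and 0.73 with an estimated correlation). With no dye term both held over all 6 samples, and both were lost without BAPTA/AM replicate 1 (adjusted p = 0.191 and 0.172) and without ionomycin replicate 1 (0.143 and 0.057). Single genes higher with ionomycin included MGP at 2.49 ± 0.21 and SLITRK6 at 2.52 ± 0.09, both well above background in 1 of the 2 BAPTA/AM samples, and, by bounds, PPP2R2C at least 5.50-fold, APBB1IP at least 3.41-fold and LRRC15 at least 3.03-fold. Genes lower with ionomycin included VCX, VCX2 and VCX3A, at -3.56 ± 0.14 to -3.25 ± 0.12, and PARD6A. The probes of these 4 genes were well above background in 1 of the 2 ionomycin samples, so the sizes are not exact. By bounds, lower genes were CT47A11 at least 3.58-fold with another probe called the other way, MIA at least 2.24-fold, GREB1 at least 1.43-fold and SYNPO2L at least 1.35-fold.

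Cytosolic ribosomal protein genes passed camera in all 3 comparisons, with medians of -0.14 for BAPTA/AM (adjusted p = 4.75e-04, and adjusted p = 0.645 with an estimated correlation), -0.05 for ionomycin (0.0411, and 0.745 with an estimated correlation) and 0.09 between the treatments (0.0387, and 0.745 with an estimated correlation). Their direction followed the dye. BAPTA/AM minus control was 1.09 within the shared array and -1.32 between the other samples, and ionomycin minus control was -1.30 and 1.23. RPL22 passed in the BAPTA/AM comparison (-0.41 ± 0.06) and between the treatments (0.50 ± 0.06), and 0 of the 74 measured members passed adjusted over the list alone. With no dye term the calls were lost over all 6 samples (adjusted p = 0.543 for BAPTA/AM, 0.737 for ionomycin and 0.727 between the treatments). In the fits that also left out 1 sample, with the dyes no longer balanced, the median turned to 0.48 for BAPTA/AM without control replicate 2 and 0.43 without BAPTA/AM replicate 2. For ionomycin it turned to 0.63 without ionomycin replicate 1 and 0.56 without control replicate 2, and between the treatments to -0.47 without BAPTA/AM replicate 2 and -0.57 without ionomycin replicate 2. Between the treatments the median was -0.02 with quantile normalization.

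The fold changes of ionomycin and of BAPTA/AM against the shared control samples correlated at r = 0.185 across the 26898 probes, which are not independent replicates. Unchanged groups against the same controls gave r = 0.501 on average over 100 simulations. The covariance was 0.0159 against a simulated 0.0121, a difference of 0.0038. Part of the relation may come from the shared controls. With a different control sample for each treatment and 1 dye within each difference, r was 0.12 for the replicates 2 of the treatments and -0.249 for the replicates 1, in which samples of a shared array entered with opposite signs. The relation thus took either sign, and with the red channel for ionomycin replicate 2 the correlation was -0.056.

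15 of the lists passed camera in no comparison. Their medians lay between -0.04 and 0.12 for ionomycin (lowest adjusted p 0.0634), between -0.20 and 0.17 for BAPTA/AM (0.101) and between -0.14 and 0.26 between the treatments (0.0717). Subunits of respiratory complex I had medians of -0.03 for ionomycin and -0.04 for BAPTA/AM over 37 members, subunits of complexes II to V -0.04 and -0.06 over 39, and genes encoded in mitochondrial DNA -0.01 and 0.02 over 6, with 0 members past limma's test in either comparison and 0 adjusted over the list alone. Regulators of mitochondrial biogenesis had -0.01 and 0.04 over 23 members, with 3 higher with BAPTA/AM over all probes and 8 higher and 1 lower adjusted over the list alone. For BAPTA/AM, the members past the test over all probes were 2 higher and 4 lower of 34 in calmodulin and calcineurin signalling (3 and 5 adjusted over the list alone), 2 and 4 of 27 in the NRF2 list (3 and 6) and 2 and 4 of 35 among apoptosis regulators (2 and 4). They were 4 and 0 of 44 in autophagy and lysosome genes (4 and 0), 2 and 1 of 30 among immediate early genes (0 and 0), 1 and 2 of 21 among antioxidants (2 and 2), 1 and 1 of 18 among metallothioneins and zinc genes (2 and 1), 0 and 1 of 14 in the iron list (0 and 2) and 0 and 2 of 9 among thyroid differentiation genes (2 and 2). For ionomycin 0 members of these lists passed over all probes, and adjusted over the list alone 2 immediate early genes, 2 apoptosis regulators and 1 thyroid gene were higher. Endothelial markers (0.12 for ionomycin and 0.17 for BAPTA/AM over 6 members) and leukocyte markers (0.07 and -0.20 over 10) had 0 members past the test in either comparison. On the array, 11 of 12 fibroblast markers, 23 of 36 epithelial genes, 9 of 19 thyroid genes, 10 of 16 leukocyte markers and 5 of 14 endothelial markers were well above background in all 6 samples.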

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

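Of the tests in this part, those of dye bias, of the array of BAPTA/AM replicate 2 as the whole cause, of the channel of ionomycin replicate 2 and of fibroblast-like cells were chosen after the results were seen, and those of a part played by that array and of chromosome copy number before.

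The channels that no label describes carried signal. In the green channel of the array of BAPTA/AM replicate 2, 65.1% of spots were well above background per the file header, and in the red channel of the array of ionomycin replicate 2, 60.4% by the flags in the file. Neither was put in a group in the main fit. The red one took the place of ionomycin replicate 2 only in the alternative named for it.

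BAPTA/AM against control gave 3200 probes past the threshold in limma and ionomycin against control 0. For ionomycin, 2714 had an unadjusted p under 0.05 (418 with the red channel for replicate 2), and 14 were called with limma's trend and robust prior. Dye bias was argued against, because the estimates BAPTA/AM 1 minus control 1 and BAPTA/AM 2 minus control 2, of opposite dye orientation and with no sample in common, correlated at 0.423 across probes. A change in the copy number of a whole chromosome in most cells was argued against too. The largest median of a chromosome with at least 100 genes was -0.046, for X. Medians over whole chromosomes cannot show a change of a part of a chromosome or in a part of the cells, which was not tested. The array of BAPTA/AM replicate 2 as the whole cause was argued against: of the 500 probes with the largest BAPTA/AM 2 minus control 1, both Cy5, 85% had the same sign in BAPTA/AM 1 minus control 2, both Cy3, where that array alone would give 50%. A part played by that array, and a response to calcium chelation, which the design names and which may account for part of the calls, stayed open; the test set beforehand gave 62.2% but decided nothing, since it compared differences of opposite dye orientation, in which genes that follow the dye take opposite signs.

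With ionomycin, the NF-kB list was higher and the ER chaperone list lower although limma passed 0 probes. At an unadjusted p under 0.05 limma had 2714 (418 with the red channel for replicate 2), and 14 were called with the trend and robust prior. Dye bias was argued against, because in estimates of opposite dye orientation both lists kept their signs and the smaller NF-kB median was 0.232. The channel taken for ionomycin replicate 2 stayed open: ionomycin replicate 1 alone gave an NF-kB median of at least 0.215 against each control sample, and without replicate 2 and the dye term both lists passed camera (adjusted p = 8.21e-11 and 4.48e-04), but with the red channel for replicate 2 the NF-kB median was 0.04 and the adjusted p 0.24. The fit without replicate 2 rests on 1 ionomycin sample, which excludes nothing about the other, and a response to raised calcium may still account for the pattern.

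With BAPTA/AM, extracellular matrix and fibroblast marker genes were lower. Dye bias was argued against, because the matrix list median was -0.279 or lower in both estimates of opposite dye orientation. Fewer fibroblast-like cells in the BAPTA/AM cultures would lower all their abundant markers. The log2 fold changes of the 5 brighter markers were all negative but spanned 0.98. PDGFRA (-1.29) and COL1A1 (-0.93) passed limma's test, while FAP (-0.35), COL1A2 (-0.35) and THY1 (-0.31) did not, so the explanation stayed open. The bound for that test was rewritten after its result was seen, since the first one, on all markers, would have excluded the explanation only through S100A4, which rose by 0.98 from a dim level and is not specific to fibroblasts. A response of the line's own cells to chelation may account for the pattern and was not tested apart from it.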

How the results depend on the processing

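The red channel for ionomycin replicate 2, the fits of only the groups compared with no dye term, and the array as a random block were chosen after seeing the data. With the red channel both ionomycin samples were Cy5, so dye was not balanced over groups in that setting. Series matrix values (scale unknown), ratios over the other channel (another group's sample or unlabelled) and the shared array as a random block with the dye term (no correlation was estimable) were not run. Dim probes, with signal near background, carry the least precision.

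Calls for ionomycin against control were 0 in most settings, 14 with limma's trend and robust prior, 1 in the fit of those groups with no dye term, and 0 to 30 leaving out 1 sample (30 without ionomycin replicate 1). For BAPTA/AM against control, 3200 became 2511 with no dye term, 3228 with quantile normalization, 1968 with median scaling, 1594 with the array as a random block, 5902 with the trend and robust prior, 402 with a fold of at least 2 and 1176 in the fit of those groups with no dye term. It was 0 with the dye term in that fit, with dim probes kept or with the red channel, and 0 to 1176 leaving out 1 sample. Between the treatments, 3995 became 2634 with median scaling, 6714 with the trend and robust prior, 441 with a fold of at least 2 and 387 in the fit of those groups with no dye term, 0 in the same 3 settings, and 0 to 1265 leaving out 1 sample. The fits leaving out 1 sample also had no dye term and left 1 group with a single dye. With no dye term and all 6 samples the counts were 0, 2511 and 3039. The cause was not tested.

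Deviations of samples with the same number correlated at -0.233 (control and BAPTA/AM), 0.223 (control and ionomycin) and -0.322 (BAPTA/AM and ionomycin). Only control and ionomycin have the same dye within a number, so the signs followed the dye. A pairing by number cannot be told apart from it. With a replicate block in place of the dye term the calls were 0, 240 and 351, and with both 0, 0 and 0. Crossing the numbers between BAPTA/AM and the other groups gives the pairing by dye, which the dye term already holds.

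Of 111 list tests, 41 passed with the preset correlation, 0 with an estimated one, 28 with fry (20 shared), 37 with no dye term, and 32 to 41 leaving out 1 sample and the dye term. Over all settings, 451 list values kept direction and call, 155 lost the call and 9 reversed. For named genes these were 866, 233 and 19, and 10 gained a call. With the red channel for ionomycin replicate 2, 30 list calls were kept, 9 lost and 2 reversed. The 12 lists called for ionomycin against control became 8 with quantile normalization and 8 with the probe of highest variance per gene. The G1/S list reversed for ionomycin with the red channel (-0.163). Cytosolic ribosomal proteins reversed for ionomycin with the red channel (0.003) and without ionomycin replicate 1 or control replicate 2 (range leaving out 1 sample -0.69 to 0.629), for BAPTA/AM without replicate 2 of it or of control (-0.709 to 0.479), and between the treatments with quantile normalization (-0.024) and without replicate 2 of either (-0.567 to 0.746). The correlation of fold changes was -0.056 with the red channel. Genes that reversed with the red channel for ionomycin were EREG -0.19, UCA1 -0.15, IDH2 0.22, HELLS -0.23, H2BC5 -0.08, SAMD9 -0.04, CXCL1 -0.43, CSF2 -0.32, CXCL2 -0.13, CDS1 -0.9, RPL3 0.01, RPL35A 0.03, LYAR -0.07 and RCAN1 0.06, and between the treatments PLCB1 -0.05 and HSPA5 0.1. The probe of MT2A, saturated in both BAPTA/AM samples and 1 ionomycin sample, gives no exact value between the treatments. With quantile normalization LDHB reversed to 0.16 for BAPTA/AM and -0.23 between the treatments, and MT2A to -0.01 between the treatments. The cause was not tested.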

Other observations

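The genes in this part were chosen after their values were seen, from lists that camera did not call for BAPTA/AM against control. BNIP3L, SLC7A11 and S100A4 are also on lists it did call, those of hypoxia targets, the ATF4 response and fibroblast markers in that order. Of the 32 genes, 31 passed limma's test, at adjusted p from 0.0185 to 0.0487. Among thyroid genes, DIO2 fell with BAPTA/AM by 1.96 on the log2 scale and FHL1 by 0.84, both at an adjusted p of 0.0185 in limma. Of 44 lysosomal and autophagy genes, 4 passed the test, all higher, where 3200 of 26898 probes passed over the whole array. The list itself did not rise: its median was -0.063, with 25 members negative. Those past the test were ATP6V0D2 at 1.83 and ATP6V1C1 at 0.51, both subunits of the proton pump that acidifies lysosomes, MAP1LC3B, an autophagosome protein, at 0.41, and the lysosomal calcium channel gene MCOLN1 at 0.45. Regulators of mitochondrial DNA that rose were TFB2M, a transcription factor, by 0.50 and TWNK, the helicase, by 0.38, while TFAM stood at 0.31 with an adjusted p of 0.0517. In calmodulin and calcineurin signalling, CAMK1D changed by -0.71, the calcineurin inhibitor gene RCAN2 by -0.64, the calcineurin subunit gene PPP3CB by -0.39 and NFATC1 by -0.39, while the calcium-binding protein genes S100A4 and S100A2 rose by 0.98 and 0.45.

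Interferon-response genes went both ways with BAPTA/AM. HLA-B, an MHC class I gene whose probe may not tell related copies apart, changed by -0.54 and TRIM22 by -0.86, while IFIT2, USP18 and ISG20 rose by 0.85, 0.83 and 0.77; with the red channel for ionomycin replicate 2, which enters the shared spread, limma called 0 probes in this comparison. Of the NRF2 list, ABCC3 changed by -1.16, NQO1 by -0.70 and SLC7A11 by -0.48, and ABCC2 by 1.00. Among apoptosis regulators BNIP3L changed by -0.79, BMF by -0.85 and APAF1 by -0.55, and the death receptor gene TNFRSF10A by 0.50. Epithelial genes were divided as well, with KRT19 at -0.65, LAMB3 at -0.65 and DSG2 at -0.56 against MUC1 at 0.92.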
